A study of Danio rerio with 4 samples.

How the data were processed

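Hepatocytes of zebrafish larvae were sequenced in 4 libraries, 1 for each of wild type and zc3h8 mutant at 5.5 and 7.5 dpf, and samples were grouped by the genotype and stage in their labels. Per the labels' protocols, livers with the lfabp:Dendra2-NTR transgene were dissected and treated with trypsin, fluorescent cells were collected on a flow sorter, RNA was taken up in Trizol and libraries were made by Smart-seq2, which amplifies cDNA by PCR without molecular identifiers. Such PCR reads are not independent molecules, so that intervals and bounds cover counting error only. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and DESeq 1.16.0 were used, with no role or order stated. The genome build, the annotation and whether counting used strand are not given in the sources used here.

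Per the file headers, the authors deposited a table of RPKM for 33737 genes in the 4 libraries, of which 17920 were above 0 in at least 1 library. The authors also deposited 4 comparison tables, which list 16578 genes between them, each with 2 columns named as normalized, a fold change (the ratio of the 2 columns), a log2 fold change, a p-value, an adjusted p-value and a mark of significance. The normalized columns were found from their values to be CPM (reads scaled to library size) as the authors deposited them. A common step per library turned 100% of the listed values above 0 reads to whole reads within a tolerance of 0.01. Whole reads were recovered from that step. Of the 44540 values of the tested genes in the 4 libraries, 1502 were not listed and were filled from the RPKM. A gene with 0 reads was listed at 0.5 of a read in the first column or at a value close to 0 in the second, and the authors' log2 fold change used the former. The authors' mark of significance stood at each gene whose deposited log2 fold change was beyond 1 in size and at no other: the authors' deposited tables marked 10511 of 14068 listed genes at 5.5 dpf (4778 higher and 5733 lower in the mutant), 10487 of 13003 at 7.5 dpf (6687 and 3800), 10005 of 13572 between stages in wild type (3611 and 6394) and 10327 of 13509 between stages in the mutant (5828 and 4499). In these 4 tables the adjusted p-value lay below the p-value for 93.2, 88.0, 94.3 and 89.8% of genes, which Benjamini-Hochberg or Bonferroni adjustment does not give. The adjustment is not given in the sources used here, so that the authors' adjusted p-values entered only an alternative count.

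The recovered reads gave the library totals. The limit that 0 reads allows, 3 reads, came to 0.0834 and 0.0825 CPM for wild type and mutant at 5.5 dpf and to 0.0811 and 0.101 CPM at 7.5 dpf. In the same order, genes above 0 numbered 13137, 10979, 9621 and 12037, and 1849, 2656, 3505 and 2205 of the tested genes were at 0. The 10 most abundant genes took 32.1, 29.0, 33.6 and 28.1% of reads. A ratio against a library with 0 reads is given as a bound against 3 reads per library ("at least"), a ratio against 1 to 3 reads is given with its counting interval or as both RPKM values, and no fold is given where both libraries had 3 reads or fewer. Counting intervals are 95% intervals of the ratio of 2 read counts.

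Symbols came from a table of gene IDs and symbols, which matched 21939 of 33737 IDs (65.0%), and 9081 of the 11135 tested genes had a symbol. No ID carried the symbol zc3h8. Where several IDs share a symbol the ID is given, and such copies are uncertain, since reads of near-identical genes could be split or lost in counting.

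Before the data were examined, the following were fixed: the 4 comparisons, the difference of log2(RPKM + 1), the minimum mean RPKM of 1, the 2-fold rule, the 36 gene lists (10 of them markers of cells other than hepatocytes), the rule for named genes and the alternatives. With 1 library per group no p-value, standard error or n applies to a gene within a comparison, and p-values came only from the count model over both stages, added later. For the 31 lists with at least 5 tested members, the median difference was set beside 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries alone. A list's median with genes at 0 reads set at 3 reads (bound median) is given where it differed from the median by 0.1 or more on the log2 scale. The 5 lists with fewer tested members (endocrine pancreas, endothelial, erythroid, and lymphoid markers, and vitellogenins with estrogen response) are given as gene values in the closing section. The ribosomal protein list was a name pattern that also took in 6 S6 kinase genes among its 76 tested members, and without these its medians were 0.31 and 0.26 in the mutant comparisons at 5.5 and 7.5 dpf and 0.01 and 0.02 between stages in wild type and mutant.

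The named genes were, for each mutant comparison, the 8 highest and 8 lowest differences among genes with a named symbol and an RPKM of at least 10 in one of the 2 libraries that also passed 2-fold with a pseudocount of 0.1 and with median-ratio scaling, and the 6 highest and 6 lowest by the smaller of both stages' differences. To these came the 4 largest differences at each stage in the inflammatory and hepatocyte lists, and, in each other list outside the central 95% of random lists at that stage, the 3 largest in the median's direction and the 1 largest the other way. The 5 highest and 5 lowest genes of each stage comparison completed the 134 named genes. List members named beyond this rule (fabp10a, apoa2, nfkbiaa, nfkbiab, tnfa, tnfb, cxcl20, myd88, isg15 and those in the closing section) and the second hspa8 gene were chosen after their values were seen. Results of some single genes, which stayed in the list counts and medians, are not reported here.

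The list percentiles and the count model were tested on simulated data. For the 5.5 dpf comparison, 100 simulated lists with no shift fell outside the central 95% of random lists in 7, 4 and 3% of cases for lists of 10, 20 and 40 genes, and lists shifted by 1 on the log2 scale did so in 40, 74 and 97%. The simulated members were drawn at random and so varied independently. These rates do not cover the real lists, whose members can vary together. The count model was edgeR 4.0.16 (quasi-likelihood) with DESeq2 1.42.0 as the alternative, in R 4.3.3, on the recovered reads of the 4 libraries with stage and genotype as terms and 1 residual degree of freedom. It assumes that the genotype effect is shared by both stages, and its estimated biological coefficient of variation was 1.66. On counts simulated for both stages over 11135 genes with 200 changed 16-fold, both tools recovered 100% at a coefficient of variation of 0.4, with 3 (edgeR) and 16 (DESeq2) false calls. Of the adjusted p-values from DESeq2 on the deposited data, 2375 were not given by the tool and were left so.

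Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean RPKM of at least 10, median-ratio scaling, the authors' log2 fold change, leaving out the marker genes of other cells, a 4-fold rule and the authors' adjusted p-value. Added after seeing the data were the restriction to genes with more than 3 reads in the libraries compared, a mean RPKM of at least 100 and the count model. Median-ratio factors were 0.955, 1.19, 0.985 and 1.31 for wild type and mutant at 5.5 and then at 7.5 dpf. On the log2 scale these factors differ by −0.04 between stages in wild type and by −0.14 in the mutant, and the median of all genes on the log2(RPKM + 1) scale moved by −0.02 and −0.04. Values of the mutant comparisons stand beside their counts. No per-sample column was left unused. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.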

Results

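Zebrafish larvae homozygous for a zc3h8 mutation were compared with wild-type larvae by RNA sequencing of hepatocytes, the main secretory and metabolic cells of the liver. The protein encoded by zc3h8 belongs to the CCCH class of zinc finger proteins, and the comparison asked how its loss bears on inflammatory gene expression and on the state of hepatocytes. Livers carrying the lfabp:Dendra2-NTR transgene, which marks hepatocytes with the fluorescent protein Dendra2, were dissected and dissociated, and fluorescent cells were sorted by flow cytometry before amplified full-length cDNA (Smart-seq2) was sequenced. There were 4 groups, wild-type and mutant at 5.5 and at 7.5 days post fertilization (dpf), with 1 library per group. There were thus no replicates. The spread between animals is unknown, no difference below has a replicate check, and the intervals and bounds given cover counting error only. Reads counted to genes were 35960983 in the wild-type and 36353835 in the mutant library at 5.5 dpf, and 36999967 and 29649005 at 7.5 dpf. Values are the deposited RPKM (reads scaled to gene length and library size). Differences are of log2(RPKM + 1), which understates the change of low genes. A mean RPKM of at least 1 was met by 11135 genes, which were held against a rule of 2-fold size.

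The most abundant hepatocyte transcripts were well covered in each library. RPKM of fabp10a, the liver fatty acid binding protein, was 20244 in wild-type and 8912 in mutant cells at 5.5 dpf, and 26723 and 7711 at 7.5 dpf. That of the apolipoprotein gene apoa2 lay between 9506 and 42933. The 13 protein genes of the mitochondrial genome took 5.70 to 6.18% of reads. Many less abundant genes had next to no reads in one library and many in another. Of the 11135 tested genes, 18.6 and 26.2% had 3 reads or fewer in wild-type and mutant cells at 5.5 dpf, and 34.2 and 23.6% at 7.5 dpf. Across genes, which are not independent replicates, the correlation of log2(RPKM + 1) between libraries lay between 0.50 (the 2 genotypes at 7.5 dpf) and 0.71 (the 2 genotypes at 5.5 dpf). No gene carried the symbol zc3h8 in the symbol table used, so the targeted gene is not analysed here and the genotype labels were not checked by it.

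At 5.5 dpf, genes for secreted liver proteins were lower in the mutant library than in the wild-type library. Transferrin (tfa), the iron carrier of plasma, was 3.75-fold lower (RPKM 2472 against 9281, 95% counting interval of the ratio 3.74 to 3.77), fabp10a 2.27-fold lower (2.26 to 2.28), and fetub, which encodes a fetuin, 3.30-fold lower. Of 25 tested hepatocyte secreted and marker genes, 3 were 2-fold higher and 8 were 2-fold lower, with a median difference of −0.63, at percentile 0.02 of 10000 random lists of the same size matched on mean expression. Where it differed, a list's median is also given with genes at 0 reads set at 3 reads (bound median). The 3 members on the other side were the apolipoprotein genes apoa1a (11.9-fold higher) and apoeb (2.31-fold higher) and the growth factor gene igf1, which went from 0 to 14.3 RPKM, at least 211-fold higher. Acute phase genes had a median of −0.61 (percentile 0.86), with 3 of 10 members lower and 0 higher. It lay at percentile 3.10 with no filter on low values and at 8.60 with a mean RPKM of at least 100. The protease inhibitor gene a2ml was 4.09-fold lower and crp3, a C-reactive protein gene, 4.47-fold lower, while the fibrinogen gene fgg was 1.47-fold higher. Complement genes were lower in 10 of 17 members with 0 higher (median −1.24, percentile 0.01). Among them were c8g (5.37-fold), c3a.2 (5.64-fold) and masp2, a protease of the lectin pathway (0.01 against 50.7 RPKM), while c4b was 2.09-fold higher. The coagulation list had a median of −0.28 (percentile 7.08), with 3 of 15 members higher and 2 lower.

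Medians of several lists of liver metabolism genes also lay below the random range at 5.5 dpf. Of all 11135 tested genes, 2847 were 2-fold lower. Bile acid and xenobiotic genes had 9 of 19 members lower and 1 higher (median −0.71, percentile 0.28, bound median −1.19). The lower genes included the cytochrome P450 genes cyp2ad2 (8.47-fold, 95% counting interval 8.21 to 8.74), cyp2ad3 (9.01-fold) and cyp2p7 (196-fold). The gene abcc2, for a transporter of bile constituents, was 2.69-fold higher. Cholesterol synthesis genes were lower in 8 of 14 members and higher in 2 (median −1.29, percentile 0.25). The low density lipoprotein receptor gene ldlra was 52.4-fold lower, sc5d 15.7-fold lower and pmvk at least 297-fold lower, whereas srebf2, a regulator of sterol genes, was 4.59-fold higher. Fatty acid oxidation genes had 5 of 24 members lower and 2 higher (median −0.46, percentile 0.73). Among them acaa1 was at 3.59-fold lower, decr2 at 3.70-fold lower and the receptor gene pparaa at 93.3-fold higher. Gluconeogenesis and amino acid genes had a median of −0.48 (percentile 1.1), with 4 of 17 lower and 2 higher. With a mean RPKM of at least 100 the fatty acid oxidation and gluconeogenesis medians both came inside the random range (percentile 4.70 each). In the latter list fbp1b was 2.51-fold lower, hgd 2.06-fold lower and kmo 2.14-fold lower, while pck1, a gene of the first committed step of gluconeogenesis, was 3.35-fold higher. Medians of fatty acid and triglyceride synthesis (−0.42, percentile 9.91) and of glycolysis (−0.37, percentile 9.98, bound median −0.74) lay inside the central 95% of random lists.

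Genes of the proteasome, which degrades ubiquitinated proteins, were higher in the 5.5 dpf mutant library. Of 37 subunits, 15 were 2-fold higher and 4 lower (median 0.90, percentile 99.7). The largest were psmb1 (5.58-fold), psmb4 (4.79-fold) and psmb3 (4.18-fold), and psmc1b was 6.15-fold lower. Nuclear genes of the respiratory chain had 18 of 88 members higher and 4 lower (median 0.49, percentile 99.3). Among these were cox6a1 (ENSDARG00000054588, 11.9-fold), ndufa1 (7.805-fold) and cox4i1l (7.03-fold), while cox4i2 went from 5.24 to 0 RPKM. Of all 11135 tested genes, 3118 were 2-fold higher, a larger share than among respiratory chain genes. Their median came from small differences, with 71 of 88 members above 0 and 17 below, and 66 within 2-fold. This respiratory chain median lay at percentile 96.4 with no filter on low values, at 97.3 among genes with more than 3 reads in both libraries and at 96.3 above a mean RPKM of 100. The p53 target list lay just inside the random range (median 0.90, percentile 94.7, 7 of 17 higher and 2 lower). In it phlda3 was at 119 RPKM against 0. Cell cycle genes had a median of 0.83 (percentile 96.2, bound median 1.09) and ribosomal protein genes one of 0.29 (percentile 82.4), which was −0.01 under median-ratio scaling. The 3 members of the ribosomal protein list that were 2-fold lower were S6 kinase genes, whose symbols matched the name pattern and which encode no ribosomal protein. The list of the little elongation complex, a transcription complex that holds Zc3h8 as a subunit, of Integrator and of small nuclear RNA transcription had 4 of 18 members higher and 7 lower (median −0.40, percentile 16.5, bound median −0.73). Inside the random range lay also the medians of apoptosis and pyroptosis genes (0.67, percentile 89.1), heat shock genes (0.57, percentile 85.0), oxidative stress genes (−0.21, percentile 7.69), hepatocyte transcription factors (−0.07, percentile 24.5) and intestine markers (−0.31, percentile 14.9, bound median −0.85). The same held for unfolded protein response genes (0.15, percentile 47.9), lysosome genes (0.14, percentile 42.4) and mitochondrially encoded genes (0.09, percentile 47.6), whose medians were −0.15, −0.12 and −0.23 under median-ratio scaling.

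At 5.5 dpf, 7 of 18 tested inflammatory genes were higher and 1 lower, and the median of 0.37 lay at percentile 70.6. This result depended on the setting. The median was 1.36 (percentile 98.6, 14 members) with the authors' log2 fold change from the authors' deposited table, 1.09 (percentile 95.8) with a mean RPKM of at least 10, 0.80 (percentile 86.4) among genes with more than 3 reads in both libraries and 0.00 (percentile 35.2) without marker genes of other cells. The chemokine gene ccl34a.4 was at 5.16 RPKM against 0 (at least 44.5-fold higher), the collagenase gene mmp13a at 15.5 against 0 (at least 395-fold). The gene tnfaip3, a negative regulator of NF-kB signalling, was 5.36-fold higher, and mmp9 went from 0 to 3.12 RPKM (at least 117-fold). The chemokine gene cxcl18b was 2.55-fold higher (95% counting interval 2.34 to 2.79). Markers of macrophages had a median of 0.09 (percentile 57.4, bound median 0.36, 7 of 16 higher and 1 lower) and those of neutrophils one of 1.26 (percentile 95.2, bound median 1.48, 6 of 9 higher and 1 lower). The interferon list of 6 genes had a median of −0.21 (percentile 33.1).

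Markers of cells other than hepatocytes moved beside these groups at 5.5 dpf. Exocrine pancreas genes, which encode digestive enzymes, were lower in 14 of 18 members and higher in 1 (median −2.80, percentile 0, bound median −5.70). The trypsin gene prss1 went from 112 to 0 RPKM (at least 1186-fold lower), prss59.1 was 159-fold lower and ela2l at least 736-fold lower. Biliary and stellate cell markers were higher in 11 of 16 members and lower in 2 (median 1.37, percentile 99.8, bound median 1.495). Of these ifitm1 was 7.64-fold higher, the smooth muscle actin gene acta2 at 6.12 RPKM against 0, vim at least 80.8-fold higher and the collagen gene col1a2 6.35-fold lower. Skin, muscle and lens genes had 9 of 20 members higher and 5 lower (median 0.86, percentile 99.5, bound median 1.04). The skin gene icn was 3.58-fold higher, the lens crystallin gene cryba4 at least 126-fold higher, pvalb3 at least 124-fold higher and the muscle creatine kinase gene ckmb 6.95-fold lower.

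Among single genes at 5.5 dpf, those with the highest differences were cartpt (ENSDARG00000035852), a neuropeptide gene, at 170 RPKM against 0 (at least 692-fold), and phlda3 (at least 2126-fold). Next came nfybb (68.3 against 0), ddit4 (66.6 against 0), vti1b (52.2 against 0), rcn1 (49.0 against 0), snu13 (ENSDARG00000069878; 48.7 against 0) and 1 of 2 hspa8 genes (ENSDARG00000037403; 48.4 against 0.04). The other hspa8 gene (ENSDARG00000068992) was at 1799.8 and 2339 RPKM in wild type and mutant. Reads shared between the copies leave the value of the first uncertain. Those with the lowest differences were tmem82 (127 to 0 RPKM, at least 1791-fold) and prss1. They were followed by agmat (68.4 to 0), nme4 (58.4 to 0), prss59.1, commd7 (55.6 to 0), the carboxylesterase gene ces3 (54.6 to 0.01) and srp9 (53.3 to 0). In all, 3118 genes were 2-fold higher and 2847 lower (4-fold: 1568 and 1668). This majority depended on the setting. Median-ratio scaling, whose factors differ by −0.31 on the log2 scale with the median of all genes at 0.00 before and after, gave 2603 higher and 3205 lower, and no filter on low values gave 3528 and 3766. Among 7201 genes with more than 3 reads in both libraries 2228 were higher and 1276 lower.

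At 7.5 dpf, the genes of secreted liver proteins were again lower in the mutant library, and leukocyte and inflammatory genes were higher. The fetuin genes ahsg1 and fetub were 8.78-fold and 10.9-fold lower, tfa was 7.01-fold lower and fabp10a 3.47-fold lower (95% counting interval 3.44 to 3.49). Of 25 hepatocyte secreted and marker genes, 18 were 2-fold lower and 2 higher (median −1.58, percentile 0), the latter being apoeb (17.2-fold) and apoa1a (59.0 RPKM against 0). Acute phase genes were lower in 7 of 10 members and higher in 0 (median −1.62, percentile 0.09). In this list crp3 was 8.68-fold, a2ml 8.14-fold and fgg 1.98-fold lower, while apcs, a pentraxin gene, was 1.22-fold higher. The serum amyloid gene saa2, an acute phase gene outside that list, went the other way, from 0 to 148 RPKM (at least 1167-fold higher). Complement genes were lower in 10 of 17 members and higher in 4 (median −1.61, percentile 0.01). The gene c8a went from 93.6 to 0 RPKM (at least 1982-fold lower) and c3b.1 from 36.1 to 0.01, while c4b was 154.5-fold higher and c3a.2 4.75-fold higher. Coagulation genes were lower in 9 of 15 members and higher in 2 (median −1.04, percentile 0.53, bound median −1.21). Among them was plg, the plasminogen gene, at 4.94-fold lower.

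Liver metabolism genes were lower at 7.5 dpf over a wide front, apart from those of cholesterol synthesis and glycolysis. Bile acid and xenobiotic genes were lower in 11 of 19 members and higher in 2 (median −1.84, percentile 0, bound median −2.30). The bile acid enzyme gene cyp8b1 went from 159 to 0.17 RPKM, 928-fold lower with a 95% counting interval of 504.5 to 1936. Of the others, cyp2ad2 was 10.7-fold lower, abcc2 3.14-fold lower and the transporter gene slco2b1 5.97-fold higher. Fatty acid oxidation genes were lower in 14 of 24 members and higher in 2 (median −1.47, percentile 0.01), including acaa1 (5.06-fold) and acox3 (at least 292-fold), with ppargc1a at least 123-fold higher. Fatty acid and triglyceride synthesis had 6 of 10 members lower and 0 higher (median −1.81, percentile 0.25, bound median −2.11). These included lpin1 (15.8-fold), dgat2 (4.88-fold) and elovl5 (at least 814-fold), and plin2, a lipid droplet gene, was 1.58-fold higher. This median was 0.00 with no filter on low values (percentile 21.3, 15 members) and lay at percentile 3.0 with a pseudocount of 5. Gluconeogenesis and amino acid genes were lower in 9 of 17 members and higher in 1 (median −1.38, percentile 0.02). The level of hgd, an enzyme gene of tyrosine breakdown, went from 434 to 0.21 RPKM, fbp1b was 7.98-fold lower, and asl, a urea cycle gene, went from 0 to 37.6 RPKM. Cholesterol synthesis genes were higher in 7 of 14 members and lower in 4 (median 0.80, percentile 62.6, bound median 1.35). Glycolysis genes had a median of −0.35 (percentile 10.5), with 2 of 9 higher and 4 lower.

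Of 18 inflammatory genes, 12 were 2-fold higher and 2 lower in the 7.5 dpf mutant library (median 2.47, percentile 99.8, bound median 2.66). The chemokine genes ccl34a.4 (125 RPKM against 0, at least 1104-fold) and cxcl18b (104-fold, 95% counting interval 89.9 to 122) were higher, as were the cytokine gene il11a (67.4 against 0, at least 549-fold) and mmp13a (43.4 against 0, at least 1139-fold). The NF-kB inhibitor genes nfkbiaa and nfkbiab were 7.05-fold and 2.35-fold higher, and tnfa and tnfb were at 8.24 against 0 RPKM and 110 against 19.1. The 2 lower members were cxcl20 (4.29-fold) and myd88, an adaptor gene of Toll-like receptor signalling (19.1-fold), and tnfaip3 was 1.76-fold lower. The list median lay inside the random range among the 12 members with a mean RPKM of at least 10 (percentile 96.7) and among the 12 with more than 3 reads in both libraries (median 0.92, percentile 88.7). Leukocyte markers were higher in the same library: 15 of 16 macrophage markers were higher and 1 lower (median 4.11, percentile 100, bound median 7.50). Likewise 8 of 9 neutrophil markers were higher with 0 lower (median 5.22, percentile 100, bound median 9.84). Among these were coro1a (80.3 RPKM against 0, at least 1795-fold), the cathepsin gene ctss2.1 (101 against 0.02), ccl34b.1 (at least 443-fold), ncf1, a subunit gene of the phagocyte oxidase (51.6 against 0, at least 1357-fold), srgn (125 against 0.06) and scpp8 (at least 913.5-fold). The macrophage marker slc7a7 was 2.81-fold lower. The macrophage median lay at percentile 96.9 among its 8 members with a mean RPKM of at least 10. Median RPKM of the macrophage markers was 25.4 in the 7.5 dpf mutant library and 0.0095 in wild type of that stage. At 5.5 dpf it was 0 in wild type and 0.14 in the mutant. Markers near 0 elsewhere could pass the filter only through the 7.5 dpf mutant library, so these leukocyte counts lean that way by construction. The interferon list had 3 of 6 members higher and 1 lower (median 1.09, percentile 67.0), with isg15 at 75.8 RPKM against 0.

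Proteasome subunits were higher in 28 of 37 members and lower in 0 at 7.5 dpf (median 1.28, percentile 99.8). Here psmb3 was 9.33-fold and psmd14 386-fold higher (81.6 against 0.21 RPKM), psmb10 was at 39.6 RPKM against 0 and psmd11 (ENSDARG00000060150) at 32.7 against 0, while psmd6 was 1.12-fold lower. The 8 subunits with a mean RPKM of at least 100 had a median of 1.18 at percentile 94.7. Respiratory chain genes had 9 of 88 members higher and 13 lower (median −0.02, percentile 3.97). Ribosomal protein genes had a median of 0.25 (percentile 78.7) that was −0.14 under median-ratio scaling. Under it mitochondrially encoded genes went from 0.21 (percentile 71.2) to −0.20 and oxidative stress genes from 0.06 (percentile 35.5) to −0.34. Medians of p53 targets (0.45, percentile 49.6), apoptosis and pyroptosis genes (0.93, percentile 77.9), heat shock genes (0.27, percentile 49.9, bound median 0.43) and unfolded protein response genes (0.53, percentile 74.3, bound median 1.04) lay inside the random range. So did those of cell cycle genes (0.92, percentile 75.3, bound median 2.38), lysosome genes (0.51, percentile 58.9), hepatocyte transcription factors (0.72, percentile 68.9) and the little elongation complex list (1.17, percentile 74.7, bound median 2.36).

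The other cell types differed in direction at 7.5 dpf. Exocrine pancreas genes were lower in 15 of 18 members and higher in 0 (median −3.65, percentile 0, bound median −5.21). The chymotrypsin gene ctrb.3 went from 161 to 0 RPKM, ctrl from 70.0 to 0, prss59.1 was 388-fold lower and prss1 3.002-fold lower. Biliary and stellate cell markers were higher in 12 of 16 members and lower in 2 (median 1.89, percentile 99.8), with krt18b 18.2-fold, ifitm1 5.16-fold and col5a1 (30.1 RPKM against 0) higher and vim 5.13-fold lower. Skin, muscle and lens genes had 9 of 20 members higher and 0 lower (median 0.54, percentile 87.5), and intestine genes 3 of 9 higher and 3 lower (median 0.00, percentile 27.7).

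The highest differences at 7.5 dpf were those of tcnba, a transcobalamin gene (686 RPKM against 0, at least 5538-fold), and cartpt (532 against 0). Then came the Wnt antagonist gene dkk1b (166 against 0), scpp5 (156 against 0), saa2, the galectin gene lgals1l1 (164 against 0.16), the glucagon gene gcga (136 against 0) and the cathepsin gene ctsh (135 against 0). The lowest were those of hgd, ahsg2 (609 to 1.77 RPKM, 344.5-fold lower with a 95% counting interval of 276 to 436), and aqp12 (199.8 to 0.07). Further down lay ctrb.3, cyp8b1, gcat (126 to 0.02), nr5a5 (121 to 0.03) and the desaturase gene fads3 (115.5 to 0.02). In all, 4456 genes were 2-fold higher and 2567 lower (4-fold: 3211 and 1791). Here the factors of median-ratio scaling differ by −0.41, which moved the median of all genes from 0.33 to 0.04 and gave 3946 and 2885. Of the higher genes 2400 had 3 reads or fewer in the wild-type library. Among 5871 genes with more than 3 reads in both libraries 2056 were higher and 1254 lower.

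**Figure D1:**
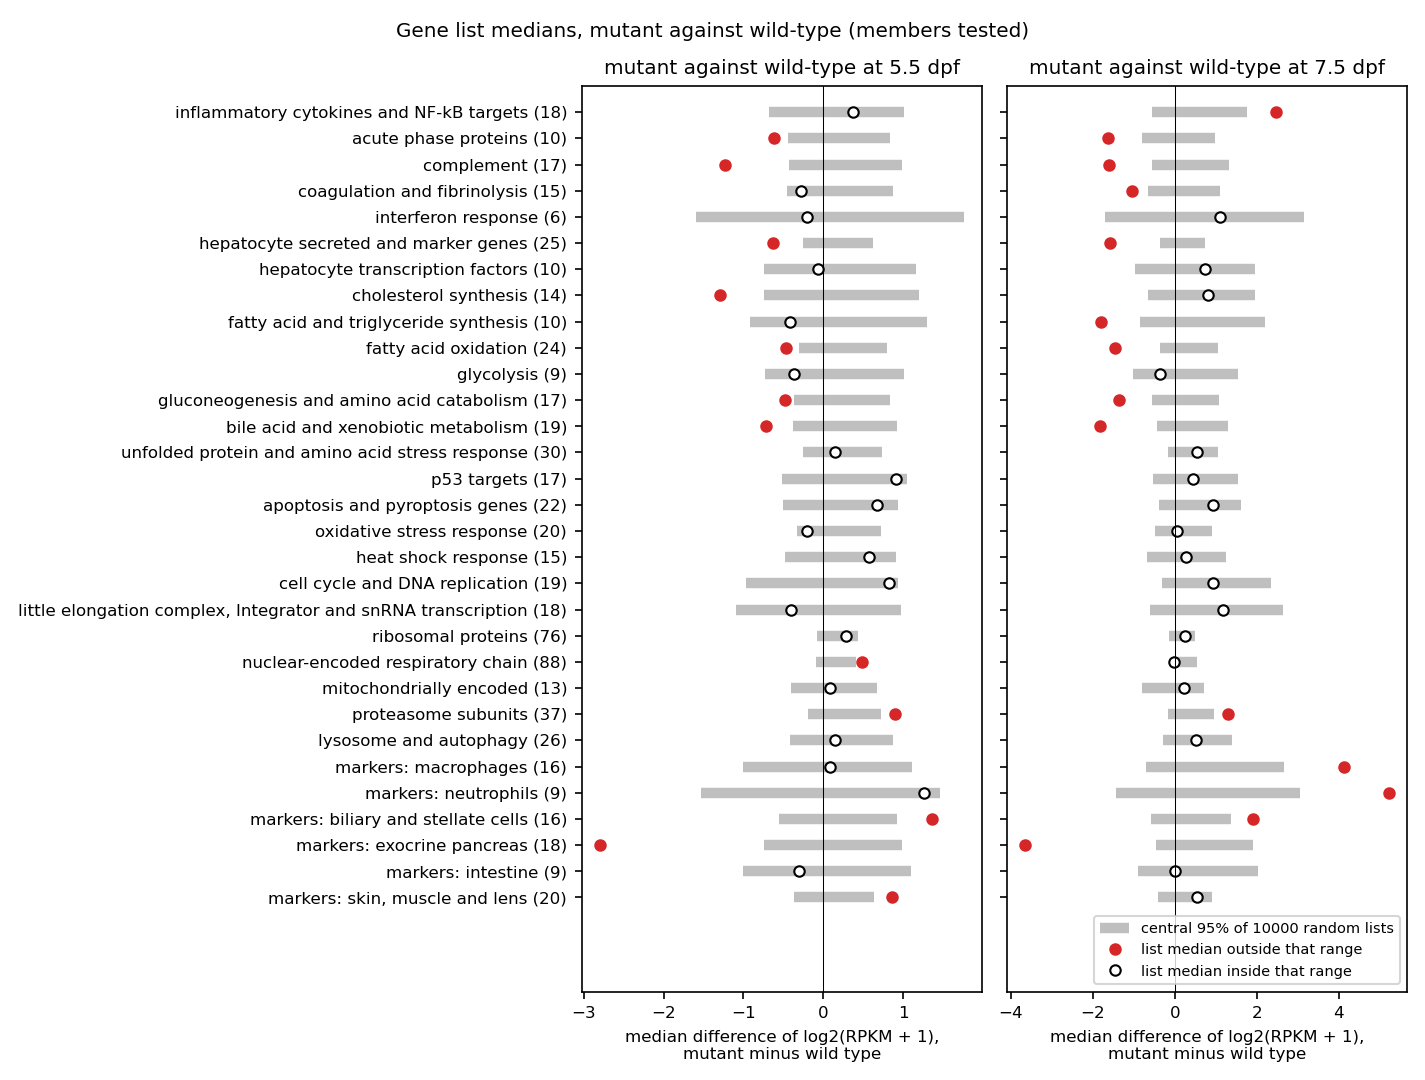
Each point is the median over a gene list's tested members (number in brackets) of the difference in log2(RPKM + 1), mutant minus wild type, at 5.5 dpf (left) and 7.5 dpf (right), with 1 library per group. Grey bars span the central 95% of 10000 random lists matched on mean expression, filled red points lie outside them, and hepatocyte genes lay at −0.63 and −1.58, exocrine pancreas genes at −2.80 and −3.65 and proteasome subunits at 0.90 and 1.28, while macrophage markers lay at 0.09 and 4.11.

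Over all tested genes, the mutant difference at 5.5 dpf had little relation to that at 7.5 dpf, and abundant genes were more alike. Higher at both stages were cartpt, phlda3 (119 and 63.8 RPKM in the mutants against 0 and 0.02), tcnba (52.7-fold, and at least 5538-fold), gng2 (78.8-fold, and at least 454-fold). To these came the mRNA 3' end processing gene cpsf2 (42.6 and 41.3 against 0.48 and 0.01 RPKM) and thoc3, a gene of the mRNA export complex THO (27.5 and 28.3 against 0). Lower at both were tmem82 (82.9 to 0 RPKM at 7.5 dpf), agmat (85.2 to 0.54), prss59.1, masp2 (46.7 to 0), cpa1 (ENSDARG00000021339; 39.9 to 0 and 98.3 to 1.87) and ugt2b1 (28.4 to 0 and 46.5 to 0.03). Of the 11135 genes, 1347 were 2-fold higher at both stages, where independent lists of these sizes would share 1248, and 861 were lower at both, where they would share 656. The correlation of both differences across genes, which are not independent replicates, was 0.12 (Pearson) and 0.12 (Spearman). Among 749 genes with a mean RPKM of at least 100, a bound chosen after the data were seen, it was 0.68 and 0.65, with 116 higher at both (39.98 for independent lists) and 58 lower at both (18.3). The mutant difference was larger by at least 1 at 7.5 than at 5.5 dpf for 4659 genes and smaller by at least 1 for 3334. A count model on the recovered reads with stage and genotype as terms, added after the data were seen, called 0 genes for genotype in either direction by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 342 genes at an unadjusted p under 0.05 (557 by chance). DESeq2 called 341 higher and 440 lower genes. On data simulated for both stages over 11135 genes with 200 genes changed 16-fold and a coefficient of variation of 1.6, edgeR recovered 0% with 0 false calls and DESeq2 24.5% with 543 false calls.

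**Figure D2:**
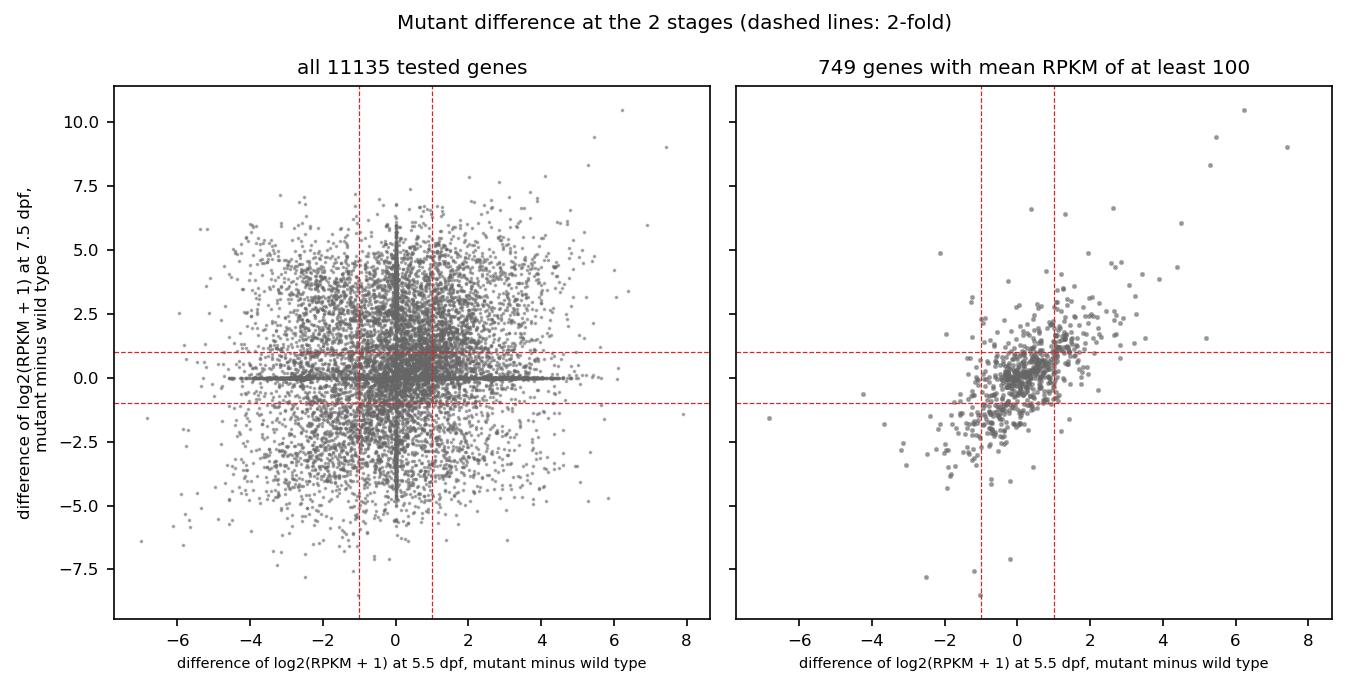
Each point is a gene, with its difference of log2(RPKM + 1), mutant minus wild type, at 5.5 dpf on the horizontal and at 7.5 dpf on the vertical axis, for 11135 tested genes (left) and for 749 genes with a mean RPKM of at least 100 (right), and dashed lines mark 2-fold. Pearson's r across genes was 0.12 on the left and 0.68 on the right.

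From 5.5 to 7.5 dpf in wild-type cells, digestive enzyme genes of the exocrine pancreas were higher and sterol synthesis genes were lower. Exocrine pancreas genes were higher in 16 of 18 members and lower in 0 (median 2.51, percentile 100). The genes with the highest single differences included the elastase gene cela1.7 (0 to 54.5 RPKM, at least 324-fold) and cel, a bile salt dependent lipase gene (0 to 43.6, at least 1042-fold). Beside them stood thoc5 (0 to 54.5), cdc42ep5 (0.02 to 51.0) and mir125b-3 (0 to 44.7). Cholesterol synthesis genes were lower in 11 of 14 members and higher in 1 (median −5.09, percentile 0, bound median −9.61). In it fdps went from 215 to 0 RPKM (at least 8043-fold), tm7sf2 from 113 to 0 (at least 2378-fold) and insig1 from 105 to 0.10. Outside the list cyp51a1, a sterol demethylase gene, went from 357 to 0.04. The chaperone gene hsp90b1 went from 111 to 0 RPKM. With it, unfolded protein response genes were lower in 15 of 30 members and higher in 1 (median −0.95, percentile 0.04, bound median −1.53). That median was 0.25 (percentile 88.7) among the 7 members with a mean RPKM of at least 100. Medians below the random range were also those of respiratory chain genes (−0.57, percentile 0.01), proteasome subunits (−0.72, percentile 0.08) and fatty acid oxidation (−0.73, percentile 0.72). Acute phase genes (−0.71, percentile 1.89) lay there too, as did the list of little elongation complex, Integrator and small nuclear RNA transcription genes (−1.55, percentile 2.38, bound median −5.89). Acute phase genes lay at percentile 4.70 with no filter on low values, fatty acid oxidation at 3.10 with a mean RPKM of at least 10 and at 3.0 with at least 100, and the last list at 6.60 among genes with more than 3 reads in both libraries. Hepatocyte secreted genes had a median of −0.20 (percentile 24.7), and inflammatory genes one of 0.00 (percentile 65.0). Biliary and stellate markers had one of 0.58 (percentile 98.3, 6 of 16 higher and 2 lower, bound median 0.82). In all, 2386 genes were 2-fold higher and 3352 lower, and 2124 of the lower ones had 3 reads or fewer at 7.5 dpf. The majority turned, to 1681 higher and 1228 lower, among 6533 genes with more than 3 reads in both libraries.

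From 5.5 to 7.5 dpf in mutant cells, inflammatory and leukocyte genes were higher, and genes of several plasma protein and lipid metabolism lists were lower. Inflammatory genes were higher in 12 of 18 members and lower in 3 (median 1.97, percentile 99.9, bound median 2.17). The chemokine gene cxcl18b was at 453 against 45.6 RPKM and ccl34a.4 at 125 against 5.16. Their median lay at percentile 95.4 among the 12 members with a mean RPKM of at least 10. Macrophage markers were higher in 13 of 16 members and lower in 0 (median 3.65, percentile 99.99, bound median 6.72). The same was seen for neutrophil markers in 7 of 9 and lower in 0 (median 2.55, percentile 97.53, bound median 2.86), and interferon genes in 4 of 6 and lower in 2 (median 3.04, percentile 98.8, bound median 5.21). With a mean RPKM of at least 10 the macrophage and neutrophil medians lay at percentiles 77.6 and 69.4. Here too, markers near 0 elsewhere could pass the filter only through the 7.5 dpf mutant library. With no filter on low values the interferon median was −0.03 over 12 members (percentile 7.10). Hepatocyte secreted genes were lower in 13 of 25 members and higher in 2 (median −1.08, percentile 0.05). So were acute phase genes in 9 of 10 and higher in 0 (median −1.93, percentile 0), and coagulation genes in 10 of 15 and higher in 3 (median −1.86, percentile 0). Complement genes had 6 of 17 members lower and 1 higher, and their median of −0.01 lay inside the random range (percentile 43.8). Fatty acid oxidation (median −1.11, percentile 0.09, bound median −1.26), fatty acid and triglyceride synthesis (−2.19, percentile 0.11, bound median −5.41), cholesterol synthesis (−1.53, percentile 0.16) and gluconeogenesis and amino acid genes (−0.94, percentile 1.07) were lower too. Respiratory chain genes were lower in 43 of 88 members and higher in 0 (median −0.99, percentile 0). Biliary and stellate markers were higher in 12 of 16 members and lower in 1 (median 1.47, percentile 99.9, bound median 1.58). Skin, muscle and lens genes were higher in 10 of 20 and lower in 3 (median 0.86, percentile 99.9), a median that was −0.01 among the 10 members with a mean RPKM of at least 100. The highest single differences were those of c1ql1 (0.71 to 508 RPKM, 713-fold with a 95% counting interval of 466 to 1152), prss1 (0 to 167), saa2, ctsh and dkk1b. The lowest were those of hgd, aqp12, cyp8b1, the amino acid transporter gene slc16a10 (97.6 to 0.03) and bckdha, a gene of branched-chain amino acid breakdown (93.3 to 0). In all, 3765 genes were 2-fold higher and 2918 lower.

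**Figure D3:**
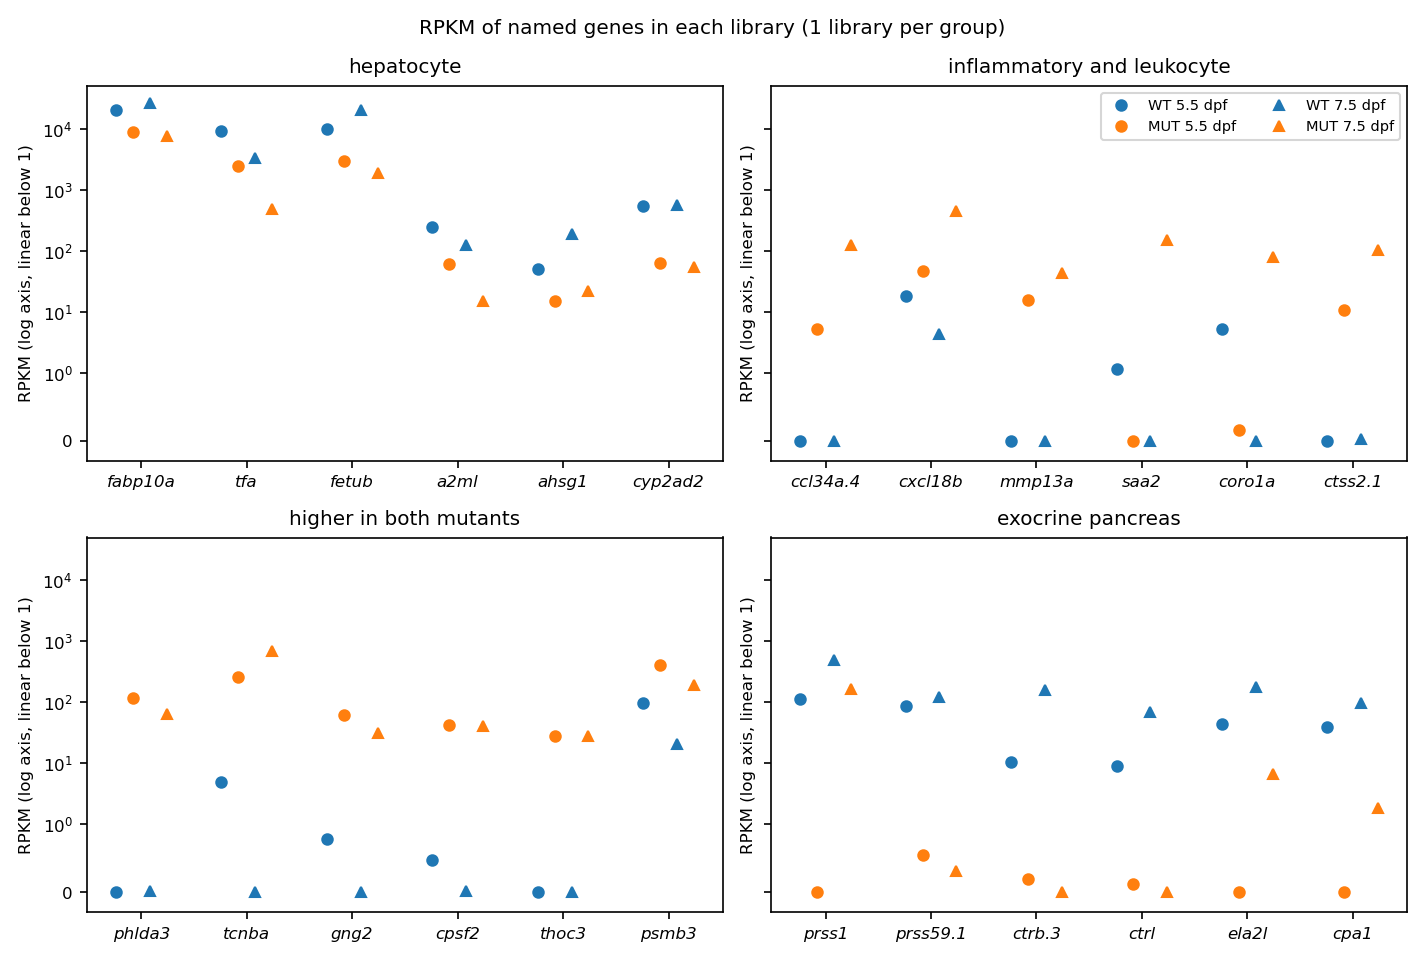
RPKM of named genes in each of the 4 libraries (blue wild type, orange mutant, circles 5.5 dpf, triangles 7.5 dpf) on a log axis that is linear below 1, for hepatocyte, inflammatory and leukocyte, mutant-high and exocrine pancreas genes. The gene tfa lay at 9281 and 3322 in the wild-type libraries and at 2472 and 474 in the mutant libraries, and coro1a at 5.31, 0.15, 0 and 80.3 in wild type and mutant at 5.5 dpf and wild type and mutant at 7.5 dpf.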

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

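Flagged were 2 gene lists and 20 named genes for which the mutant library lay on one side of the wild-type library at 5.5 dpf and on the other side at 7.5 dpf. A list also had to have a median in the outer 2.5% of random lists at 1 stage or more, and a gene to be past 2-fold at both stages. Other lists and named genes changed side without meeting these rules. Of all 11135 tested genes, 456 were 2-fold higher and then 2-fold lower, where independent lists would share 719. Lower and then higher were 937, where they would share 1139. Some flagged genes rest on a library at or near 0 reads. Thus commd7 had 0 reads in the 5.5 dpf mutant, and coro1a had 10 there and 0 in wild type at 7.5 dpf. With 1 library per group the difference between stages was not tested. The tests of sterol gene loss by chance, of stage, of a lower hepatocyte share, of dilution, of amplification noise and of genotype, and the choice of leukocyte genes by the other 3 libraries, were chosen only after the result was seen, while the test of sequencing depth and the set of leukocyte genes were written before.

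Values here are the mutant minus wild-type difference at 7.5 dpf minus that at 5.5 dpf, in log2(RPKM + 1). The cholesterol synthesis median moved by 2.09 and the respiratory chain median by −0.51. Among sterol genes cyp51a1 moved by 7.01, fdps by 6.32 and srebf2 by −4.91. Lower and then higher in the mutant were also lgals1l1 (10.35), ctsh (9.62), coro1a (8.80), saa2 (8.34), psmb10 (7.56), commd7 (7.12), c3a.2 (4.25), psmc1b (3.73) and col1a2 (3.29). Higher and then lower were vti1b (−7.35), pparaa (−7.11), snu13 (ENSDARG00000069878; −6.70), slc16a10 (−6.42), slc7a7 (−4.50), thoc5 (−3.93), vim (−3.62) and abcc2 (−3.04).

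The change of direction of sterol synthesis genes rested on the 7.5 dpf wild-type library, where 6 of the 14 list members had 3 reads or fewer, against 0, 1 and 4 in the wild-type 5.5 dpf, mutant 5.5 dpf and mutant 7.5 dpf libraries. Sequencing depth argued against itself as the cause: at that library's depth these members would have had a median of 3909.9 reads (1172 to 11667) from their mean RPKM in the other libraries. Chance loss of single transcripts gave as many in 1.45% of random lists matched on expression (median 2, upper end of their central 95% 5), which leaves it open, since this list was picked from 31 for its values. A joint loss of sterol transcripts in those cells or in that library may also be the source, and stage is open too: the mutant libraries moved the same way between stages (median −1.53), but each stage and genotype had 1 library. The wild-type stage difference and the 7.5 dpf mutant difference share this library, so neither is a check of the other.

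Leukocyte genes that were higher in the 7.5 dpf mutant library are a candidate explanation for the inflammatory shift there, as transcripts of leukocytes among the sorted cells rather than of hepatocytes, although the sort for Dendra2 was meant to remove such cells. Of 30 leukocyte genes outside the fixed lists, written down before their values were seen, 15 matched and 9 were tested, but 4 of these passed the filter only through their value in that library. Of the 5 with a mean RPKM of at least 1 in the other 3 libraries, 100% were 2-fold higher (exact 95% interval from 47.8%), against 31.0% of all genes chosen that way, with cd63 at 1819 RPKM against 405, arpc1b at 128 against 0 and rac2 at 49.1 against 3.35. These are few, and 4 of them had an RPKM of at least 1 in a wild-type library, where their source in leukocytes or other cells is unknown. Of the 15, 3 were at 0 in all 4 libraries. The neutrophil gene lyz was at 0 RPKM in that mutant library, and npsn was at 0 in all 4 libraries and so tells nothing. Leukocytes as the source thus stay open. A lower share of hepatocytes alone would raise other cells' markers alike, whereas exocrine pancreas genes had a median of −3.65 in the same comparison. That median cannot decide on the hepatocyte share, since the 7.5 dpf wild-type library was itself high in these genes. Against the 5.5 dpf wild-type library, 16 of 18 were higher there and 0 lower (median 2.51). Whether genotype or this 1 library brought the leukocyte transcripts cannot be told apart.

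Lower hepatocyte genes in both mutant libraries might come from dilution by RNA of other cells, from amplification noise or from the genotype, which cannot be told apart from other differences between libraries with 1 library per group. Dilution alone would lower abundant hepatocyte genes by 1 common factor, so that they spread no more than other genes of like abundance: over 12 hepatocyte and acute phase genes with a mean RPKM of at least 500, the SD of the differences was 2.36 times (95% bootstrap interval 1.204 to 3.47) that of 26 ribosomal protein genes at 5.5 dpf and 3.01 times (1.75 to 4.51) at 7.5 dpf. Both intervals lie above 1, but this cannot decide on dilution as the whole cause, since ribosomal protein genes may spread less than hepatocyte genes for other reasons. Between the 2 wild-type libraries, which differ in stage, 3 of 25 hepatocyte secreted and marker genes were 2-fold higher and 2 lower. Of the 76 members of the ribosomal protein list, 1 was higher and 1 lower there. The bootstrap also resampled genes of 1 pair of libraries, which are not replicates. Dilution as a part of the shift stays open too. Independent noise would put about 25% of the 12 hepatocyte and acute phase genes lower at both stages, and 91.7% were (11 of 12, 95% Wilson interval 64.6 to 98.5%). The shares at each stage alone also gave 91.7%, so this count does not separate a shared cause from 2 separate ones. A wider set chosen after those results (41 genes with a mean RPKM of at least 100 over 4 lists, against 50) gave SD ratios of 1.94 (1.46 to 2.504) and 5.14 (2.84 to 7.63) and 68.3% lower at both stages (53.02 to 80.4%, 60.4% if independent).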

How the results depend on the processing

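The alternatives with more than 3 reads, a mean RPKM of at least 100 and the count model were chosen only after the data were seen. With 1 library per group no replicate could be left out. The count model holds stage as a term and so compares the genotypes within each stage. Counts are genes 2-fold higher and lower, and unless a construction shows it (fewer genes tested, a stricter rule) the cause was not tested. Leaving out the marker genes of other cells moved no count by over 1.5 times. It left 11036 of 11135 genes, too many for any count to move that far, so this is no check.

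A 4-fold rule gave 1568 and 1668 genes at 5.5 dpf and 1219 and 2040 between stages in wild type. The authors' adjusted p-value lay under 0.05 for each gene they listed, in all 4 comparisons, so this rule took out no listed gene. Its counts are the listed tested genes by the sign of the authors' fold, with no rule of size. They were 5393 higher and 4681 lower at 5.5 dpf, 4358 and 5487 between stages in wild type and 4590 lower between stages in the mutant. The authors' log2 fold change gave a correlation of both stages of 0.0885 and an inflammatory median of 1.36 at 5.5 dpf, which then lay at percentile 98.6 of random lists. A mean RPKM of at least 10 gave 1245 and 762 at 5.5 dpf, 1685 and 891 at 7.5 dpf, 820 and 1041 between stages in wild type, 1182 and 1000 in the mutant, 719 and 292 at both stages, a correlation of 0.24, 1437 and 1086 genes moved up and down between stages and an inflammatory median of 1.09 at 5.5 dpf. A pseudocount of 0.1 gave a correlation of 0.0859, and one of 5 gave 1450 lower at 5.5 dpf, 1545 and 1740 between stages in wild type, 765 and 405 at both stages, a correlation of 0.20 and an inflammatory median of 1.57 at 7.5 dpf. Median-ratio scaling gave hepatocyte medians of −0.94 and −1.98.

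With more than 3 reads there were 1276 lower at 5.5 dpf, 2056 and 1254 at 7.5 dpf, 1228 lower between stages in wild type, 1964 and 1402 in the mutant, 631 and 287 at both stages, a correlation of 0.21, 1417 and 1257 moved up and down and inflammatory medians of 0.80 and 0.92. A mean RPKM of at least 100 gave 116 and 58 at both stages and a correlation of 0.68. The count model gave 0 and 0 genes by edgeR (342 at an unadjusted p under 0.05) and 341 and 440 by DESeq2.

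Of list medians in the outer 2.5% of random lists, those that changed sign were of interferon genes between stages in the mutant (−0.034 with no filter on low values), and, with a mean RPKM of at least 100, unfolded protein response genes between stages in wild type (0.25) and skin, muscle and lens genes between stages in the mutant (−0.0074). Median-ratio scaling turned 10 further medians that lay inside the random range. Those between stages in the mutant were of p53 targets (0.13 to −0.003), proteasome subunits (0.02 to −0.11) and ribosomal protein genes (0.02 to −0.12), and the others stand beside their medians in the mutant comparisons. Of 49 medians in the outer 2.5%, 31 stayed there in each setting that left the list at least 5 members, among them hepatocyte genes in both mutant comparisons. Settings that left fewer members were passed over and not counted as a loss. With a mean RPKM of at least 100, 24 stayed and 9 came inside. Median-ratio scaling took out 0, but it moves a list and its random lists nearly alike. At 5.5 dpf, acute phase genes lay at percentile 3.10 with no filter and 8.60 with a mean RPKM of at least 100, where fatty acid oxidation and gluconeogenesis genes both lay at 4.70. Of 373 differences of named genes past 2-fold, 12 came inside 2-fold under median-ratio scaling and 35 with a pseudocount of 5. A change of sign was seen for 0, but no setting tried could turn a difference of that size, so this is no check. Named genes taken for the highest and lowest differences had also been chosen as past 2-fold with a pseudocount of 0.1 and with median-ratio scaling.

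At these depths 3 reads are 0.0811 to 0.101 CPM, yet 18.6 to 34.2% of tested genes had 3 or fewer in a given library. These shares did not follow depth. The share was 34.2% in the library with the most reads (wild type at 7.5 dpf, 36999967). It was 23.6% in that with the fewest (mutant at 7.5 dpf, 29649005). Folds of such genes are bounds on 1 library each.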

Other observations

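All values in this part were chosen after they were seen, and no hypothesis was tested on them.

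Islet hormone genes were higher in the 7.5 dpf mutant library. The insulin gene ins was at 24.97 RPKM and the somatostatin gene sst1.2 at 9.65 RPKM, and both were at 0 in the other 3 libraries, so that they were at least 149-fold and 115-fold higher than in the wild-type library of that stage. The glucagon gene gcga, at 136 RPKM there, was also at 7.71 RPKM in the 5.5 dpf mutant library and at 0 in both wild-type libraries. Exocrine pancreas genes were lower in the same library than in the wild-type library of that stage. Against the 5.5 dpf mutant library, 9 of 18 were 2-fold higher and 1 lower (median 1.08, percentile 94.8, bound median 3.21). Genes of blood and vessels were also seen there: the plasmalemma vesicle gene plvapa was at 9.82 RPKM against 0 in the other 3 libraries, the B cell receptor gene cd79a at 32.5 and in the 5.5 dpf mutant at 26.0 against 0 in wild type, the erythrocyte carbonic anhydrase gene cahz at 14.2 against 0 in the other 3, and f13a1b, the only tested member of the vitellogenin and estrogen response list, at 42.6 against 0 at 7.5 dpf. Of the other tested endothelial and lymphoid markers, plvapb was at 6.60 RPKM against 0.31 at 7.5 dpf, runx3 at 4.95 against 0 and sox7 at 28.8 against 16.9, within 2-fold, and at 5.5 dpf they were at 0 against 0.68, 0 against 0.05 and 26.8 against 6.03. The globin genes hbae3 and hbae1.1 were not specific to that library: hbae3 was at 7.89 and 19.1 RPKM in wild type and mutant at 5.5 dpf and at 0 and 39.7 at 7.5 dpf, and hbae1.1 at 4.13 and 0, then at 0.43 and 0.43.

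Some stress genes inside lists whose medians lay in the random range differed in the same direction at both stages. The ubiquitin ligase gene mdm2 was 5.03-fold and 39.8-fold higher in the mutant libraries, while cdkn1a, a cell cycle inhibitor, was 6.46-fold higher at 5.5 dpf and 1.69-fold lower at 7.5 dpf and tp53inp1 was 4.25-fold and 2.31-fold lower. Of the unfolded protein response list, some genes were higher at both, with manf at 3.87-fold and 5.34-fold, pdia4 at 3.51-fold and 2.90-fold, creld2 at 3.98-fold and at least 368-fold, hyou1 at 3.21-fold and at least 1099-fold and hsp90b1 at 1.59-fold and at least 3471-fold. Others were not: calr was 1.04-fold lower at 5.5 dpf and 2.31-fold higher at 7.5 dpf, dnajb11 was 1.38-fold higher and then 2.77-fold lower, and the stress transcription factor genes ddit3 (134 and 115 RPKM in wild type and mutant at 5.5 dpf, 268 and 220 at 7.5 dpf) and atf4b (159 and 161, then 156 and 146) stayed within 2-fold. The glycolysis gene pklr, the liver pyruvate kinase, was 5.67-fold and 7.88-fold lower, and gapdhs was 7.36-fold and 24.5-fold higher beside a 1.67-fold and 6.08-fold lower gapdh. In the list that holds the little elongation complex, eaf2 was at 30.2 and 18.5 RPKM in the wild-type libraries and at 0 and 0.02 in the mutant libraries, while the related gene eaf1 was at 8.0 and 0 in wild type and at 33.4 and 14.0 in the mutants.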
